A study of Mus musculus with 250 samples.

How the data were processed

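The series holds 250 single cells that the titles call brain astrocytes, each a sample of its own, from adult C57BL/6 mice. The mice carry SM22-Cre with a Rosa26 reporter. SM22 is the protein of the smooth muscle gene Tagln, and Cre under its promoter removes a stop in front of the red fluorescent protein tdTomato. Per the labels' protocols, brain cells were sorted by fluorescence into wells, with a gate that is not given in the sources used here, and full-length cDNA of polyadenylated RNA was made in each well with the Smart-seq2 method. This method has no molecular identifiers, so a read is not an independent molecule. The names of the cells in the table headers have 2 prefixes, Brain.VSMC2 and Brain.VSMC3, followed by a well position. VSMC is a usual short form of vascular smooth muscle cell, although the titles say astrocyte. The prefixes are called plate 2 (162 cells) and plate 3 (88 cells) here and are treated as technical batches. The labels name no animal, so the 250 cells are 1 group without known replicates. Cells are not replicates, and no test, p-value or standard error was computed from them.

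The deposited count table, per the file's own values, holds whole-number read counts that were not normalized. It has 24490 gene rows, of which 16367 have at least 1 read and 8123 have none. The authors' second deposited table holds a score per gene and cell, which is the count scaled to a total of 500000 per cell and rounded. This was tested on every entry, and 100% were equal to that calculation. Per the submitters' processing notes, STAR 2.4.2a and the mouse build mm10 were used. The counting tool, its strand setting, the annotation and the filter that chose these cells are not given in the sources used here. The table has 813 gene names with a numbered suffix or a plus sign, and these were kept as they stand. It has 0 mitochondrial and 0 spike-in rows, so neither could be used for cell quality. All 250 columns were matched to a sample by name, and 0 columns were left unmatched. No cell was removed. There were 0 pairs of identical cells, and the highest correlation between cells was 0.463. No doublet caller was run, because cells were sorted into single wells and are few. Cells with markers of another type were counted in its place.

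Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. They are 1-based and were used only to say where a gene lies.

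Levels are CPM, a gene's deposited count divided by the cell's total count and scaled to 1000000. A gene was called detected in a cell at 10 CPM or more. Means are over cells, and the spread given with them is the SD between cells. Log values are log2(CPM + 1). Shares of cells carry exact (Clopper-Pearson) binomial intervals at 95%, and sums of reads carry exact Poisson intervals. Both cover counting error only, since reads copied by PCR are not independent molecules and cells of 1 animal are not independent animals. A count of 0 was read as allowing up to 3, so 0 of 250 cells allows a share of up to 1.2%.

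The gene lists were fixed before the data were examined, as were the measures, the rule for named genes and the first set of alternatives. The 36 lists hold 271 different genes, of which 268 have a row. They are markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, neurons, microglia and macrophages, endothelial cells, smooth muscle, pericytes, fibroblasts, ependymal cells, choroid plexus, Bergmann glia, red blood cells and proliferating cells. Further lists are telencephalic, non-telencephalic and Gfap-high astrocytes, forebrain and caudal transcription factors, 11 functional lists, 4 reactive or stress lists, sex-linked genes and a background list of genes of other tissues. The text names the 20 genes with the highest mean, members of the fixed lists, the 20 most variable genes and the 10 highest and 10 lowest ratios between the plates. Values of some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

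Variable genes were ranked by the excess of log squared coefficient of variation (CV) over a loess trend on log mean CPM (statsmodels 0.14.6). The trend was fitted on each plate separately, and genes were ranked by the lower of their excesses. A gene needed a mean of 20 CPM on both plates, and no cell could hold 10% or more of its total. The loess span of 0.1 was chosen after rankings at several spans had been seen, because wider spans left the most abundant genes above the trend. A running median was used first. Spans of 0.3 and 0.05 and the running median are given as alternatives. Co-variation of a list is the mean pairwise Spearman rho of its members over cells, computed within each plate and averaged. A member had to be detected in 5 cells. Each list was set against 10000 random lists matched member by member to genes of nearest mean level, as a description of these cells. Lists in the top 2.5% of their random lists were called. Clusters were made with the Leiden method in scanpy 1.11.5 at resolution 1, with 15 neighbours, 20 principal components and 2000 variable genes. All fixed lists were left out of the clustering. Plate ratios are log2 of (mean CPM + 1) on plate 3 over plate 2. They were taken among genes with a mean of 20 CPM on either plate, where no cell held 25% or more of the gene's total on the higher plate. Random deals of the 250 cells into groups of 162 and 88 were made 100 times for scale. Pooled size factors came from scran 1.30.0 in R 4.3.3. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

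The methods were tested on simulated data made from the real levels and depths. In the simulated plate comparison of 6940 genes, 200 were changed, and log2 changes of -2, -1, 1 and 2 came back with medians of -1.99, -0.93, 0.86 and 1.97. Of the 20 genes picked there as extreme, 3 were among those changed and the others were not, so being named in the plate comparison is weak evidence of a change. Of 20 genes made variable, 19 were ranked among 5044 genes and 10 were in the highest 100. All 3 lists made to vary together were in the top 2.5% of random lists, and 0 of 3 unchanged lists were. For 3 simulated groups with switched-on genes, 4 clusters were found, with an adjusted Rand index of 0.703 and 100% of cells in a cluster led by their own group. For 3 groups whose genes were raised 5-fold, 10 clusters were found, with an adjusted Rand index of -0.00626 and 52% of cells in a cluster led by their own group, the share of the largest group.

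The alternatives tried were detection at 1 read or 50 CPM, the authors' normalized table, cells thinned to 50000 reads, each plate alone, scran size factors, sums of counts and leaving out the highest cell. For co-variation they were Pearson correlation, correlation given depth and genes detected, and a filter on members. For clusters they were other resolutions, gene numbers, seeds and centring. The oligodendrocyte list left out, the factor Nr2e1 left out, the sums of Tagln reads without the highest cell of a plate and the changes of the trend were added after the data had been seen.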

Results

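The data are full-length transcriptomes of 250 single cells from the adult mouse brain, all titled astrocytes and forming 1 group. The comparisons open to such a design are of astrocyte genes against those of other cell types, of gene groups with each other, of cells with each other, and of the 2 plates. The cells held 72773548 counted reads, 40517737 on plate 2 and 32255811 on plate 3. The median cell had 282290 reads, with a range of 102161 to 564958. The median was 256247 on plate 2 (n = 162 cells) and 391072 on plate 3 (n = 88 cells). A median of 2400.5 genes per cell was detected at 10 CPM, 2367 on plate 2 and 2512.5 on plate 3. Detection of single genes was uneven, since 969 of the 16367 genes with reads (5.92%) were detected in at least 50% of the cells and 34 in every cell. The median correlation of log levels between cells was 0.374, with 0.373 for cells of the same plate and 0.376 for cells of different plates. There are no known biological replicates, so each value below describes these cells.

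**Figure D1:**
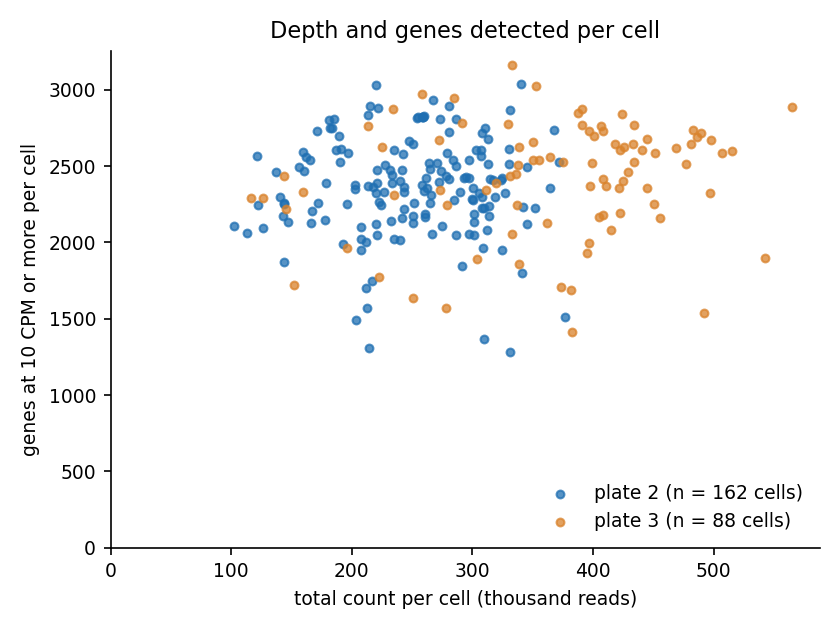
Total count per cell (x axis) against genes at 10 CPM or more (y axis), one point per cell, coloured by plate. The median depth is 256247 reads on plate 2 and 391072 on plate 3.

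The cells carried the transcripts that define astrocytes, at levels and spreads that differed between markers. Gja1, the main gap junction protein of astrocytes, had a mean of 7116 ± 2967 CPM (SD between cells, n = 250). Aldoc, a glycolytic aldolase of astrocytes, had 5910 ± 2874 CPM, the neurotensin receptor gene Ntsr2 had 5355 ± 1933 CPM, and the glutamate transporter gene Slc1a2 had 4385 ± 2310 CPM. All 4 were detected in all 250 cells. Slc1a3, the other main glial glutamate transporter, was detected in 248 cells, and the water channel gene Aqp4 in 244. The transcription factor gene Sox9 was detected in 217 cells, the folate enzyme gene Aldh1l1 in 214, with 511 ± 494 CPM, and the calcium-binding protein gene S100b in 192, with 301 ± 374 CPM. Each cell had 11 to 16 of the 16 astrocyte markers, with a median of 15. The filter that chose these cells is not given. If it used expression, these counts and the low counts of other types and of Tagln may follow from it. Gfap, the intermediate filament often used to stain astrocytes, was the 1 marker below 50% of cells, with 32 cells (12.8%, 95% interval 8.92 to 17.6%). Its share was 8.02% on plate 2 and 21.6% on plate 3, while its highest cell reached 4471 CPM. Gja1 lies on chromosome 10 at 56377330 to 56402513, Aqp4 on chromosome 18 at 15389496 to 15410982 and Gfap on chromosome 11 at 102887336 to 102900912 (GRCm38).

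The 20 genes with the highest mean held 18.9% of all reads, and 18 of them were detected in every cell. The nuclear noncoding RNA Malat1 was highest at 32735 ± 21528 CPM. Apoe, the main lipid carrier protein of the brain, followed at 18731 ± 7119 CPM. The ribosomal RNA precursor Rn45s had 17006 CPM, the protease inhibitor gene Cst3 15256 CPM and the secreted matrix protein gene Sparcl1 14977 ± 4983 CPM. Clu, which codes for another lipoprotein of the brain, had 8425 CPM. The sodium pump subunit gene Atp1b2 had 7714 CPM. Gpr37l1, a receptor gene of glia, had 7455 CPM, Cpe 6776 CPM, Cd81 6059 CPM, Ndrg2 5183 CPM, Prnp 4766 CPM and Ppap2b 4573 CPM. The GABA transporter gene Slc6a11 had 4326 ± 1759 CPM, and Agt, which codes for angiotensinogen, had 4320 ± 2842 CPM. Gja1, Aldoc, Ntsr2 and Slc1a2 are the 4 of the 20 that belong to the astrocyte list. Apoe lies on chromosome 7 at 19696109 to 19699188, Slc6a11 on chromosome 6 at 114131241 to 114249952 and Agt on chromosome 8 at 124556534 to 124569706.

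**Figure D2:**
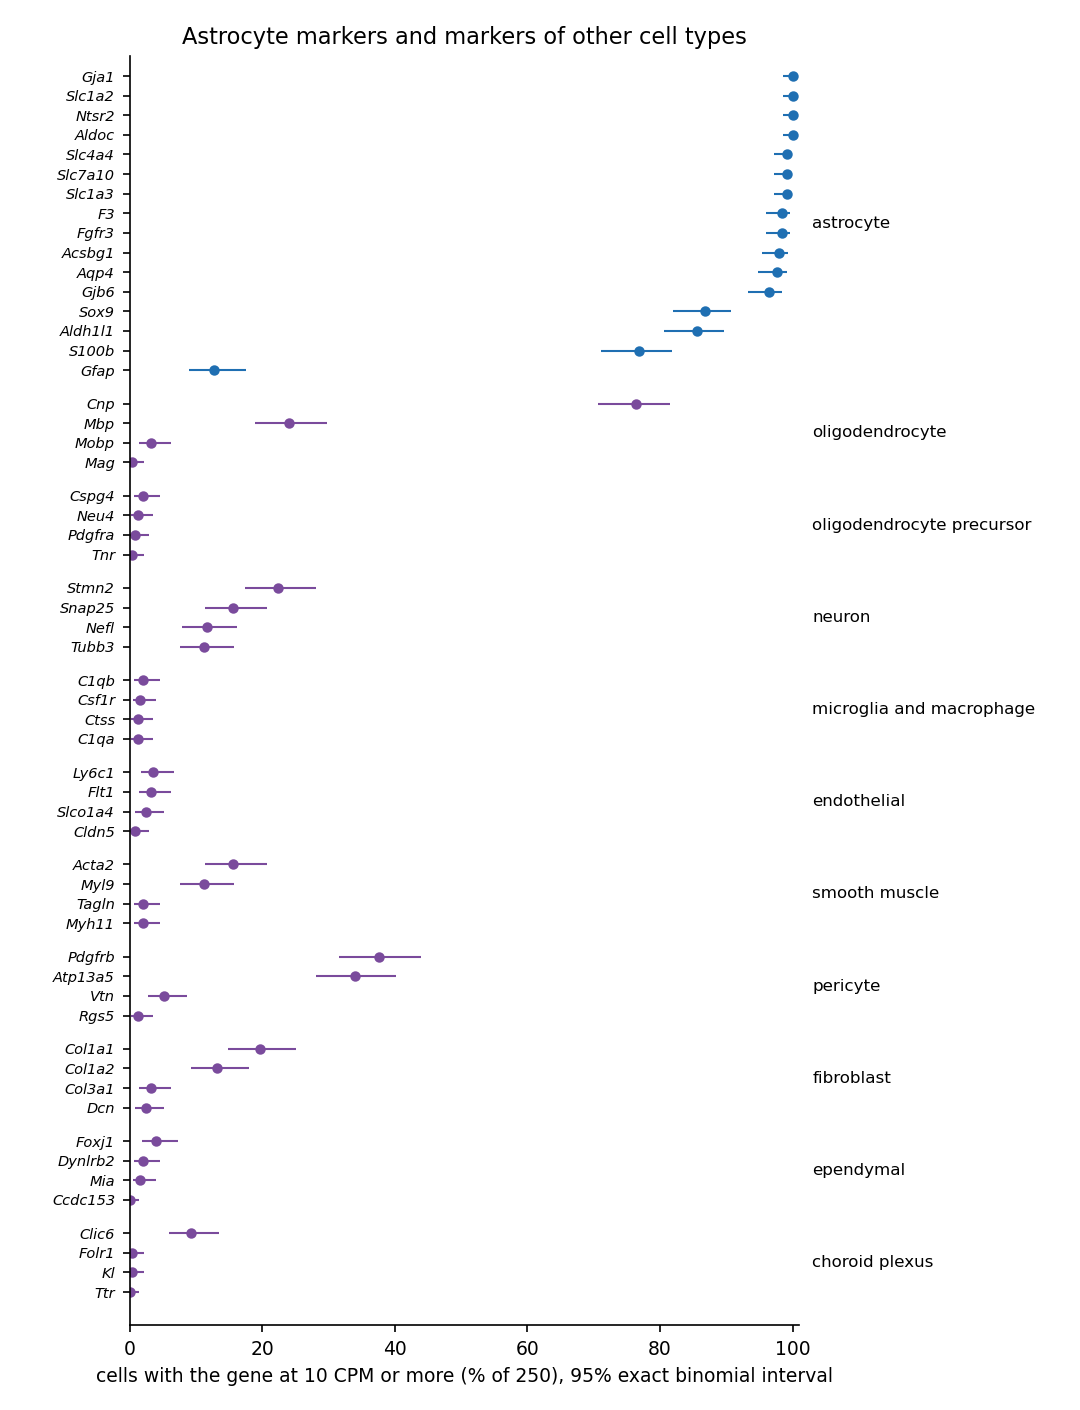
Percent of the 250 cells in which each marker was detected at 10 CPM or more, for all astrocyte markers and up to 4 markers of each other cell type, with bars for the exact 95% binomial interval. Gfap, at 12.8%, is the astrocyte marker farthest below the others.

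At least 3 markers of another brain cell type were detected at 10 CPM in 44 cells (17.6%, 13.1 to 22.9%). This share depends on the threshold, with 78.4% at 1 read, 27.6% in cells thinned to 50000 reads and 11.2% at 50 CPM. Of these types, oligodendrocytes accounted for 31 cells (12.4%), neurons for 6, pericytes for 3, microglia for 2, and endothelial cells, smooth muscle and fibroblasts for 1 each. No cell had 3 markers of oligodendrocyte precursors, ependymal cells, choroid plexus or dividing cells, and 0 of 250 cells allows a share of up to 1.2%. Among the markers behind the oligodendrocyte share were Cnp, an enzyme of myelinating cells, in 191 cells and the myelin basic protein gene Mbp in 60. The myelin genes Mog, Mag, Mobp, Cldn11 and Ermn were detected 2 or more at a time in 0 cells. With the oligodendrocyte list left out, a choice made after the data were seen, 14 cells (5.6%, 3.10 to 9.22%) had 3 markers of another type.

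Among other single markers, the growth factor receptor gene Pdgfrb was detected in 94 cells, the transporter gene Atp13a5 in 85, the neuronal genes Stmn2 and Snap25 in 56 and 39, and the collagen genes Col1a1 and Col1a2 in 49 and 33. The precursor marker Cspg4 was detected in 5 cells, the cilia gene Foxj1 in 10 and the choroid plexus marker Clic6 in 23. The cell division gene Mki67, the choroid plexus gene Ttr and the haemoglobin gene Hbb-bs, the 1 red blood cell marker with a row, had no reads. Of the 16 background genes of other tissues, 11 had no reads. The exception among the rest was Myh6, a heart muscle myosin, with 22.4 CPM and 68 cells.

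Tagln, the gene whose promoter drives Cre in these mice, was close to silent. It was detected in 5 of 250 cells (2.0%, 0.653 to 4.61%), and 58 cells (23.2%) had at least 1 read. Its sum was 117 reads (97 to 140) on plate 2 and 37 reads (26 to 51) on plate 3. A single cell held 61 of the reads on plate 2, and without the highest cell of each plate, a choice made after the data were seen, the sums were 56 and 34 reads. Of the contractile genes of smooth muscle, the actin gene Acta2 was detected in 39 cells with a mean of 6.80 CPM, the myosin light chain gene Myl9 in 28 cells, the myosin heavy chain gene Myh11 in 5 and Tpm2 in 3. Cnn1 and Des were detected in 0 cells at this threshold, although 5 and 16 cells had a read. Tagln lies on chromosome 9 at 45929619 to 45936058. At 1 read the share of Tagln cells was 23.2%, so the value depends on the threshold.

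Genes of transmitter uptake and ion transport were widely detected. All 8 genes of glutamate and GABA uptake were detected in at least 50% of the cells, among them the glutamine transporter gene Slc38a3 at 1306 CPM, Abat, which breaks GABA down, at 627 CPM and the glutamine synthetase gene Glul, lowest at 575 CPM. A cell had at least 5 of these 8. All 8 genes of potassium, water and bicarbonate transport were too, among them the bicarbonate transporter gene Slc4a4 at 2289 CPM, the potassium channel gene Kcnj10 at 836 CPM and the sodium pump regulator gene Fxyd1 at 188 CPM. Of these, a cell had a median of 7 and at least 4. Of the endfoot genes 5 of 6 passed, with Mlc1 highest at 1474 CPM and the cell adhesion gene Hepacam next at 1153 CPM. Of the gap junction genes 2 of 3 passed, and the third, Gjb2, had 84.2 CPM.

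Most genes of lipid synthesis and export passed as well. Of the cholesterol synthesis genes 9 of 11 passed, led by the sterol oxidase gene Msmo1 at 2070 ± 1594 CPM and the epoxidase gene Sqle at 430.2 CPM, while the isomerase gene Idi1 had 3.77 CPM. Of the lipid export genes 4 of 5 passed, and the exporter gene Abcg1 was detected in 10 cells. Of the glycolysis and glycogen genes 5 of 9 passed, with the lactate dehydrogenase gene Ldhb at 827 CPM and the glycogen synthase gene Gys1 at 65.1 CPM.

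Signalling groups had both widely and rarely detected members. Of the synapse-regulating and phagocytic genes 2 of 9 passed, Sparcl1 and Sparc, while the phagocytic receptor genes Megf10 and Mertk were detected in 117 and 110 cells and the thrombospondin gene Thbs1 in 0 cells. Of the vascular signals 4 of 7 passed, with the growth factor genes Ptn at 368 CPM and Vegfa at 73.2 CPM, and with Shh detected in 1 cell. Of the receptors 6 of 13 passed, with the endothelin receptor gene Ednrb at 2148 CPM and the adrenergic receptor gene Adra1b at 13.2 CPM. Of the Notch pathway genes 2 of 7 passed, Notch1 at 235 CPM and Notch2 at 206 CPM, and the ligand gene Dll1 had no reads. In all, 55 of the 86 genes of the functional lists were detected in at least 50% of the cells, beside 5.92% of all genes with reads.

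Genes of reactive astrocytes and of acute stress were low. Over all 250 cells, none of the 50 genes of these 4 lists was detected in at least 50%. The lists are pan-reactive (13 genes), A1 (11), A2 (12) and immediate early and stress (14). Of all genes with reads 5.92% passed, so this count says little by itself. The protease inhibitor gene Serpina3n led the pan-reactive list at 122 CPM and 64 cells. It had 44.4 CPM and 11.1% of cells on plate 2 and 265 CPM and 52.3% on plate 3. Lcn2, a secreted marker of strong reactivity, was detected in 2 cells. Amigo2 at 123 CPM and Fbln5 at 83.8 CPM led the A1 list, and S100a10 at 11.6 CPM led the A2 list. The immediate early gene Fos had 27.5 CPM and was detected in 60 cells, and Btg2 had 59.5 CPM in 34 cells. Hspa1a, a heat shock gene that rises with tissue handling, was detected in 1 cell. How reads that match more than 1 gene were counted is not given, so the low count of Hspa1a does not show that handling was mild. Of the Gfap-high astrocyte markers, Id3 had 217 CPM in 102 cells and Vim 17.5 CPM in 30 cells, and 19 cells (7.6%, 4.64 to 11.6%) had 3 or more of the 8.

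Markers of astrocytes outside the telencephalon were in most cells, and so was 1 telencephalic marker, Mfge8. Of the 7 non-telencephalic markers, the transporter gene Slc6a11 was detected in 250 cells, Agt and the matrix gene Sparc in 247 each, Itih3, which codes for a hyaluronan-binding protein, in 242 and the glycine transporter gene Slc6a9 in 239. The transcription factor genes Irx2 and Irx5 were detected in 35 and 27 cells. Of the telencephalic markers, Mfge8, a secreted phagocytosis protein gene, was detected in 244 cells, while the forebrain factor genes Lhx2 and Emx2 were detected in 4 and 1 cells. Bergmann glia markers of the cerebellum were in few cells, with A2m in 34, Gdf10 in 27 and Wif1 in 0.

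A caudal transcription factor was detected in 110 cells (44%, 37.8 to 50.4%) and a forebrain factor in 56 (22.4%, 17.4 to 28.1%). Irx3 was the most frequent caudal factor, in 48 cells, En1 and En2 were in 17 and 5 cells, and the 4 Hox genes had no reads. Both kinds were found in 22 cells, where independence would give 24.6, a ratio of 0.893. Most forebrain calls came from Nr2e1, detected in 45 cells. Without it, a choice made after the data were seen, 16 cells had a forebrain factor and 2 had both, where independence would give 7.04, a ratio of 0.284. This ratio rests on 2 cells and has no interval, so it does not show that the kinds exclude each other.

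The genes that varied most between cells, for their level and on both plates, included the regional markers Itih3, Sparc and A2m. After Malat1, Itih3 ranked second among 5079 genes, with a mean of 4189 CPM and quartiles of 1352 and 6148 CPM. Its CV was 0.975 on plate 2 and 0.958 on plate 3, and its squared CV was 3.97 times the fitted trend on plate 3, the plate with the lower excess. Nnat, an imprinted gene of a small membrane protein, had a median of 678 CPM with quartiles of 47.5 and 2043 CPM. Igsf1, an X-linked immunoglobulin superfamily gene, had a mean of 1249 CPM in 191 cells. Lcat, which esterifies cholesterol in lipoproteins, had 784 CPM in 179 cells, and Hsd11b1, which regenerates active glucocorticoid, 611 CPM in 159 cells. Others of the 20 were Adam11, Slc38a1, Crot, Pls3, A2m, Omg, Sgpl1, Slc1a3, Rnf139, Mbp, Rev3l, Ppp1r3c and Sparc. Adam11 was detected in 60 cells, and Slc1a3 in 248. The rank correlation of the excess over the trend was 0.671 across genes between the plates, where genes are not independent replicates, and 28.5% of genes lay above the trend on both. Itih3 lies on chromosome 14 at 30908572 to 30923760, Nnat on chromosome 2 at 157560078 to 157562522, Igsf1 on chromosome X at 49782536 to 49797749 and Lcat on chromosome 8 at 105939551 to 105943382.

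Genes of some pathways varied together from cell to cell. The cholesterol synthesis genes had a mean pairwise rho of 0.0927 over cells, 0.0981 on plate 2 and 0.0874 on plate 3, where matched random lists had a median of 0.0127. Fdft1, which makes squalene, and Msmo1 had a rho of 0.295 and 0.276 on the plates, and the first pathway enzyme gene Hmgcs1 and Fdft1 had 0.268 and 0.287. The non-telencephalic markers had 0.121, with Sparc and Itih3 at 0.526 and 0.366 and Agt and Itih3 at 0.438 and 0.428. The factor genes Irx2 and Irx5 of this list had 0.226 and 0.251 with each other. With Agt, Itih3, Sparc and Slc6a11 they had only -0.119 to 0.103 on the plates, so the list did not vary as a whole. The potassium, water and bicarbonate genes had 0.0862, with Aqp4 and the carbonic anhydrase gene Car2 at 0.299 and 0.351. The smooth muscle genes had 0.101 and the glycolysis genes 0.0489. These 5 of 26 lists lay in the top 2.5% of their random lists, where 0.65 lists would by chance, and 0 lay in the bottom 2.5%. The astrocyte markers had 0.0134 and the receptors -0.00586. The smooth muscle list fell out of the top when cells were thinned to 50000 reads, at 0.0210, and on plate 2 alone, at 0.0680. The potassium, water and bicarbonate list did so by Pearson correlation, at 0.0797, and on plate 2 alone, at 0.0643, and the glycolysis list given depth and genes detected, at 0.0155, and on plate 3 alone, at 0.0499. Correlations here are over cells of unknown animals and carry no test.

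**Figure D3:**
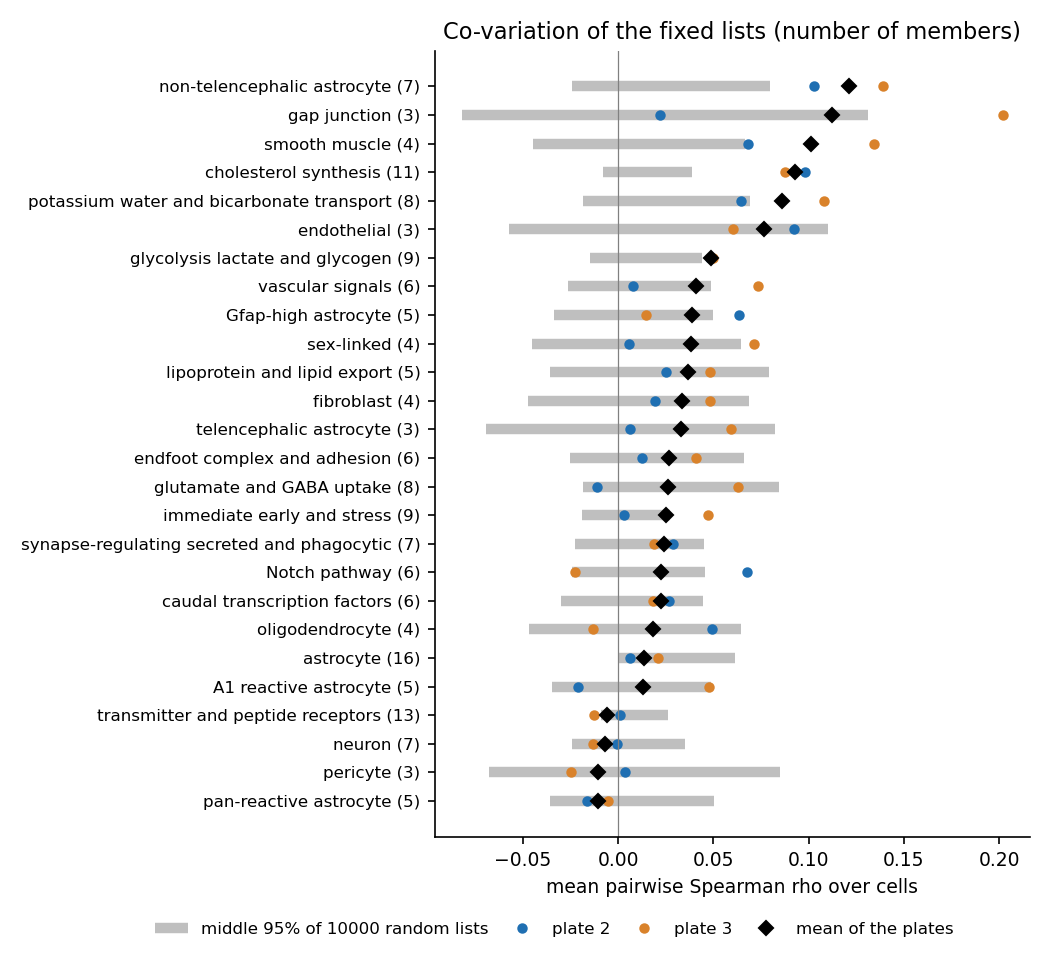
Mean pairwise rho over cells for each fixed list with 3 or more members, by plate and as the mean of the plates, beside the middle 95% of 10000 random lists. The random lists are means of the plates too. Cholesterol synthesis, at a mean of 0.0927, lies above the middle 95% of its random lists.

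Clustering gave no stable division into named types. The cells fell into 8 clusters of 19 to 41 cells with a silhouette of 0.0319, while the same data with each gene shuffled gave 10 clusters and 0.0220. The summed astrocyte markers ranged from 34989 to 44545 CPM between clusters, a ratio of 1.27, and glutamate and GABA uptake genes from 17653 to 22953 CPM. The Bergmann glia markers, led by A2m and Gdf10, ranged from 0.713 to 252 CPM. Only 1 marker of a cell type was among the leading genes of any cluster, so the clusters were left unnamed. Leading genes had to be detected in at least 50% of a cluster's cells, which kept sparse markers out. In the simulated data, groups whose genes were raised 5-fold were not recovered (adjusted Rand index -0.00626), so groups that differ in this way could be missed. The first principal component followed the number of genes detected, with a rank correlation of 0.905 over cells.

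Levels of abundant genes correlated between the plates, but their median absolute log2 ratio exceeded that of all 100 random deals of the cells. The reactive astrocyte gene Serpina3n had a higher mean on plate 3. Serpina3n had 44.4 CPM on plate 2 and 265 CPM on plate 3, a log2 ratio of 2.55, and was detected in 18 of 162 cells (11.1%) and 46 of 88 cells (52.3%). In 100 random deals of the cells its log2 ratio spanned -1.01 to 1.00, a range computed for this gene alone, after its values were seen. It lies on chromosome 12 at 104406729 to 104414329. Among 1530 genes of at least 100 CPM on both plates, the correlation of log2 levels was 0.963 and the median absolute log2 ratio 0.20, beside 0.15 to 0.17 in random deals. Tspan15 (-1.17), Nnat (-0.98), Pnpla7 (-0.98), Hibadh (-0.96) and Hmgcs1 (-0.94) had the lowest log2 ratios of plate 3 to plate 2 among these, and Lars2 (1.14), Slc7a2 (0.98), Lphn1 (0.97), Dmxl2 (0.94) and Dbp (0.93) the highest. These 10 were ranked among abundant genes after the data were seen. In random deals the highest abundant ratio was 0.80 to 1.31 and the lowest -1.29 to -0.76.

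Over all 6964 genes compared, the correlation was 0.893 and the median absolute log2 ratio 0.37, above the 0.31 to 0.33 of random deals. The lipoprotein receptor gene Vldlr had the highest ratio at 3.17, with 5 cells on plate 2 and 12 on plate 3, and lies on chromosome 19 at 27216484 to 27254231. It was followed by 1600002H07Rik, Ctc1, Wnt3, Serpina3n, Dpysl3, Sh3rf1, Ccdc138, A830082K12Rik and Sema6a, down to 2.22. The lowest were Mfsd9, which had 1202 reads in 10 cells on plate 2 and 0 on plate 3, Zfp438 (-4.46), Lancl2 (-4.35), Fam107b (-4.14), Zfp623, Itpkc, Ccdc32, Cep19, Zfp560 and Csgalnact2, up to -3.19. In random deals the last of the 10 highest ratios was 1.83 to 2.37 and the last of the 10 lowest -3.88 to -2.37, while the highest was 2.21 to 5.16. The highest ratio and the last of the 10 each way lie within these ranges. The 2.55 of Serpina3n does not exceed the highest ratios of random deals, but each of those is the largest over all genes compared. For Serpina3n alone, chosen after its values were seen, random deals spanned -1.01 to 1.00, so these ranges answer different questions.

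**Figure D4:**
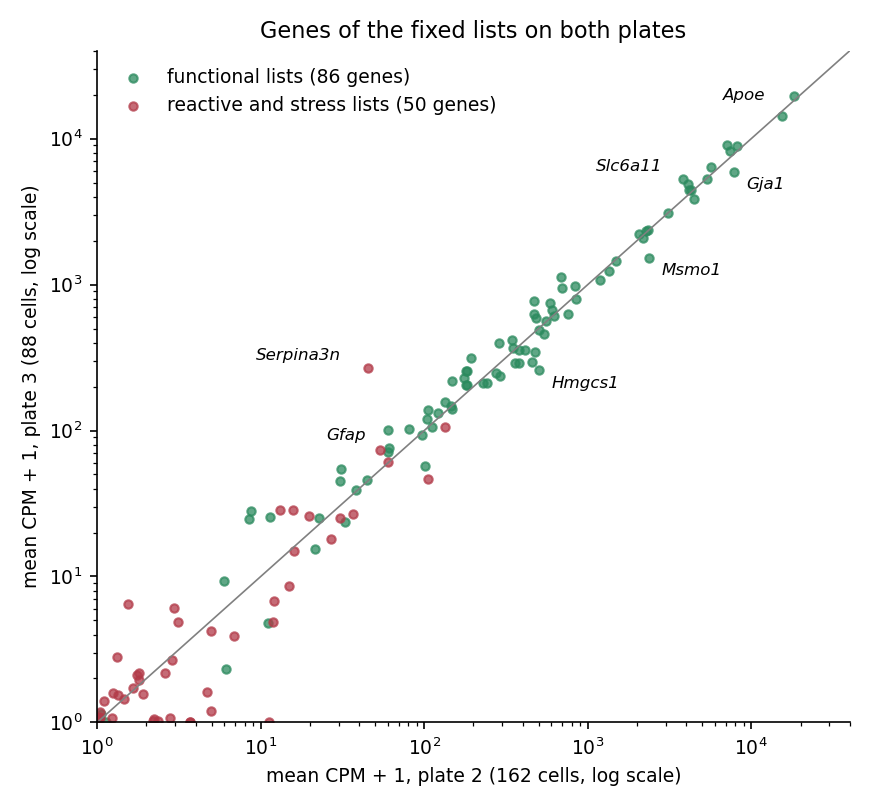
Mean CPM + 1 on plate 2 (x axis) and plate 3 (y axis), on log scales, for the 86 genes of the functional lists and the 50 of the reactive and stress lists, with a line where both are equal. Serpina3n lies at 44.4 and 265 CPM.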

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

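The alternatives without the oligodendrocyte list, Nr2e1 or the cell with most Tagln reads on a plate and those with another trend for variable genes were chosen after the data were seen, and the others before. No paired analysis was possible because there is 1 group and no test. No called value changed sign under the alternatives run.

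The median number of genes detected was 2875 at 1 read and 1945 at 50 CPM, and astrocyte markers had a median of 14 at 50 CPM. The share of cells with 3 markers of another type was 78.4% at 1 read, 11.2% at 50 CPM, 27.6% in cells thinned to 50000 reads and 5.6% without the oligodendrocyte list. The share with Tagln was 23.2% at 1 read and 6.8% after thinning. A single read is worth 20 CPM after thinning, which by construction lowers the threshold to 1 read. The ratio of cells with both kinds of regional factor was 0.284 without Nr2e1, resting on 2 cells. Gfap was at 8.02% on plate 2 and 21.6% on plate 3, and the cause was not tested.

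Smooth muscle co-variation was 0.0210 after thinning and 0.0680 on plate 2, and had no value among members detected in 20% of cells. Potassium, water and bicarbonate genes had 0.0797 by Pearson correlation and 0.0643 on plate 2, below the top 2.5% of random lists. Glycolysis genes had 0.0155 given depth and genes detected, and 0.0499 on plate 3, also below it. The cause was not tested. Gap junction, Gfap-high, Notch and immediate early lists entered the top under some alternatives. Cholesterol synthesis and non-telencephalic markers stayed in the top 2.5% under each alternative run. Clusters numbered 2 at resolution 0.5 and 14 at 1.5, and the adjusted Rand index to the clusters reported was 0.135 to 0.684 over the alternatives. Ranked by share of cells detected, the plates kept 1 of the 20 named genes, Serpina3n, which was kept in each plate alternative. Of the variable genes at least 16 of 20 were kept. Of the levels of 116 named genes, 24 changed over 1.5 times without their highest cell, among them Xist, Lhx2 and Cd109. The levels of 5 genes, Abcc9, Ccnb2, Hspa1b, Shh and Xist, did so with counts summed over cells. At the median depth a gene of 10 CPM has 2.82 reads, so shares of cells for low genes move with the threshold.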

Other observations

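The tests of whole endothelial cells, stray reads, cells sharing a well, shared Atp13a5 reads and selection of Nnat partners were chosen after the results were seen. Those of plate position, depth, scaling and brain region were set before. Genes in this part outside the fixed lists were chosen after their values were seen.

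The metal-binding metallothionein genes varied together between cells. Mt1 and Mt2 had a rho of 0.521 on plate 2 and 0.739 on plate 3, and Mt1 and Mt3 had 0.574 and 0.519, at means of 1053, 311 and 474 CPM. Itih3 had a positive rho with the glutamate transporter gene Slc1a3 (0.435 and 0.515) and a negative one with the carbonic anhydrase gene Car2 (-0.512 and -0.342) and the water channel gene Aqp4 (-0.334 and -0.401). Serpina3n had a rho of 0.0650 and 0.175 with Gfap, -0.0162 and -0.0180 with S1pr3, -0.0207 and -0.146 with Aspg, and -0.0545 and 0.000768 with Vim, all genes of reactive astrocytes. The pseudogene Rpl14-ps1 and its parent Rpl14 had 0.849 and 0.895, and whether they share reads was not tested.

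Sex-linked genes were read as a group of their own. A Y-linked gene was detected in 202 cells (80.8%, 75.4 to 85.5%), with Eif2s3y in 154, Ddx3y in 80, Uty in 42 and Kdm5d in 35. Xist, which silences an X chromosome in females, was detected in 4 cells, 2 of which also had a Y-linked gene, and 46 cells had neither.

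Traces of vascular genes were spread over nearly all cells. A read of at least 1 of 12 endothelial, smooth muscle or pericyte genes was in 247 cells, with a median of 4 genes per cell. The reads of some genes lay mostly in few cells. The 5 highest cells of a gene held from 12.5% (Ly6c1) to 84.0% (Rgs5) of its reads, and 1 cell had 999.9 CPM of Myl9. Whole endothelial cells in most of these wells are argued against, since 0.526% (0.0133 to 2.90%) of 190 cells with an endothelial read had 3 endothelial genes at 10 CPM. Whole smooth muscle cells or pericytes were not tested in this way and stay open. In cells with a read, the 12 genes had a median of 3.97 CPM beside 144 CPM for matched genes. This put them at a median percentile of 0, but the 12 were chosen without the higher Pdgfrb and Atp13a5. Stray reads of vascular RNA and low expression in the astrocytes therefore both stay open, and no biological explanation was tested. Plate row and column held 34.4% of the variance beside 24.7 to 42.0% in shuffled positions, so exchange between wells cannot be told apart from none, because the value lies inside the shuffled range.

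Single markers of other types, among them Mbp, Cnp, Snap25, Pdgfrb and Atp13a5, averaged 50 CPM or more. A second cell in the well is argued against, since a median of 0% of cells with such a marker had 2 further markers of its type. Snap25 had the highest share at 12.8%, beside 9.00% of cells without it. Reads of Atp13a5 shared with its neighbour Atp13a4 are argued against too, since their rho was at most 0.0784 on a plate. Expression of these genes in astrocytes stays open, and no biological explanation was tested.

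Nnat varied together with other genes, and of 20 partners chosen on plate 2, all 20 kept their sign on plate 3, among them Cd9 (0.465), Apoe (0.482) and the non-telencephalic markers Sparc (0.462), Agt (0.433) and Itih3 (0.287) with Nnat, and Htra1 (-0.414) and Gria2 (-0.406) against it, although Car2 and Uqcrc2 were near 0. The mean signed rho on plate 3 was 0.311, above the highest of 1000 other genes treated alike (0.277). This argues against selection of the partners as its whole source. Nnat itself was picked from both plates as a variable gene, and the 1000 genes were not matched to it in variability, so selection of Nnat stays open. The mean signed rho was 0.287 given depth and genes detected, which argues against these as its whole source. Scran size factors gave 0.309, but relative to total counts they varied between cells with an SD of 0.10 and 0.08 (log2) on the plates, too little to test scaling, which stays open. The summed score of Nnat and its partners had a rho of -0.180 and -0.0970 with caudal minus forebrain factors, opposite in direction to its non-telencephalic partners, so whether a regional source may contribute stays open and cannot be told apart from none, since 106 cells carried none of these factors.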
